A study of Mus musculus with 6 samples.

How the data were processed

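The libraries came from liver sinusoidal endothelial cells of C57BL/6 mice, taken on day 14 after partial hepatectomy (PHx, surgical removal of part of the liver) or after a sham operation. Per the labels' protocols, the cells were purified with magnetic beads against CD146, a surface protein encoded by Mcam, RNA was extracted with Trizol, and libraries were sequenced as read pairs on an Illumina instrument. Each group held 3 libraries, numbered 1, 3 and 4 in both groups. The labels do not state that the libraries came from separate animals; p-values then measure only the spread between these samples, which may be technical.

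A single deposited table gave, for every gene and library, a whole-number count and an RPKM value. The submitters' processing notes name bcl2fastq, TopHat2 2.0.13 and the mouse build mm10 (GRCm38). The counting program, the annotation release, the use of strand and whether a count stands for a read or a read pair were not given in the sources used here. Reads from overlapping genes, antisense partners and near-identical copies can therefore not be told apart in these counts. The deposited RPKM values equalled the count divided by the gene length in the table and by the library's summed counts for 100% of values, at a relative tolerance of 1e-06. The deposited length, in base pairs per gene, was used only for that check, and the counts were used for all tests.

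The table held 48897 genes, of which 17208 had a count of 0 in all libraries. 27 gene names had been turned into dates, as spreadsheet programs do, and were restored through the Entrez gene numbers in the table. A check of 39064 genes against the RefSeq table of GRCm38.p6 found that 99.8% overlapped the position listed there. No row was without a name, and no value column was left without a sample. Summed counts per library ranged from 38765116 to 51888481. A count of 0 allows up to 3 counts, or between 0.0578 and 0.0774 CPM, the usual scaling of counts by library size, and this floor covers counting error only. The libraries were compared in pairs by a chi-square statistic per degree of freedom, which was at least 55.7 in every pair, so no library was a copy of another.

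Differences were tested with edgeR 4.0.16 in R 4.3.3, using trimmed-mean-of-M-values (TMM) scaling, filterByExpr and robust quasi-likelihood F-tests, with group as the only term. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 among the 19033 genes that passed the filter. Standard errors (SE) were derived as the absolute log2 fold change divided by the square root of F. CPM values are TMM-scaled and are given as mean ± SD over 3 libraries. Averages over lists use log2 CPM with a prior count of 2.

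40 gene lists, for endothelial functions, signalling, stress, metabolism and markers of other cell types, were fixed before the data were examined. Each was compared with all other genes by camera in limma 3.58.1, with a preset inter-gene correlation of 0.01 on voom values, two-sided, and with adjustment over the 40 lists. Camera was repeated with an estimated correlation, and limma's fry was run as a directional test of each list on its own. 4 listed genes were not matched to a name in the table.

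The genes named were set by a rule fixed at the same time. It took up to 10 called genes per direction with the largest change, no overlap between the groups and a mean of at least 5 CPM in the higher group. It also took up to 4 called members of each list, or the most abundant members where none was called, and a fixed set of endothelial, growth factor and cell-type genes whatever their values. Genes outside the rule appear only in the closing section and are named there as such.

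The model was tested on simulated counts for the same 19033 genes, with 100 genes changed at a log2 size of 1 and 100 at a log2 size of 2. It recovered 26% of the smaller and 65% of the larger changes, all with the correct sign, and 11 of its 106 calls (10.4%) were false. Another 4 calls fell among 20 genes shifted for the list test. In the same simulation camera called a shifted list and did not call an unshifted one. The simulated genes were drawn independently of each other, so this cannot test the preset correlation.

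The alternatives were other scaling factors, other filters on low counts, DESeq2 1.42.0, limma-voom, stricter thresholds, the replicate number as a block, a hepatocyte marker covariate, and leaving out each library in turn. Alternatives planned for RPKM values alone were not run, since counts were present. Intervals of list medians are 95% bootstrap intervals over genes from 10000 draws, and genes of a list are not independent. All 10 ways of dividing the 6 libraries into groups of 3 were also fitted.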

Results

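RNA of purified mouse liver sinusoidal endothelial cells, the fenestrated and scavenging lining of the liver's capillaries, was compared between PHx and sham on day 14 after the operation. The 3 sham libraries held 38765116, 51888481 and 49729956 counts and the 3 PHx libraries 48638220, 49611423 and 48488625. Between 24704 and 26230 genes had at least a single count per library. Mitochondrial transcripts took between 1.20% and 1.35% of the counts in the sham libraries, and 2.36%, 1.33% and 1.56% in PHx 1, 3 and 4. Mcam, which encodes the protein used for purification, stood at 342 ± 53.3 CPM in sham and 369 ± 37.3 CPM in PHx (SD, n = 3), a log2 fold change of 0.11 with an adjusted p of 0.783.

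The comparison asked which transcripts differed between cells from PHx and sham mice on day 14. Of 27 collagen and matrix genes 12 were higher after PHx, as were 9 of 18 stellate, 4 of 13 smooth muscle and 2 of 9 mesothelial markers. None of these lists passed when camera estimated the correlation, while fry passed all but the mesothelial list (fry adjusted p = 0.0592). Col3a1, a chain of type III collagen (chromosome 1, 45311538 to 45349706, mm10), rose from 229 ± 19.9 to 1306 ± 239 CPM, a log2 fold change of 2.51 ± 0.18 (SE, n = 3 per group). Col1a2, a chain of type I collagen (chromosome 6, 4505618 to 4541543), rose from 128 ± 13.1 to 875 ± 351 CPM. Fn1, which encodes fibronectin (chromosome 1, 71585473 to 71653234), rose from 273 ± 34.7 to 882 ± 70.6 CPM. Galnt15, an enzyme that starts O-linked glycan chains (chromosome 14, 32028657 to 32062204), fell from 176 ± 9.10 to 71.1 ± 6.72 CPM.

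In total 161 genes were higher and 3 were lower after PHx at an adjusted p under 0.05 in edgeR's quasi-likelihood test. Of the higher genes, 138 changed by at least 1 on the log2 scale. In all 164 genes the PHx libraries lay on one side of the sham libraries, as they did for 20.5% of all tested genes, where chance gives 10%. The smallest adjusted p was 0.00558, and the median log2 fold change over all tested genes was 0.03. The number of calls rested on every library except PHx 4. The higher and lower counts were 0 and 0 without Sham 4, 6 and 1 without Sham 3, 34 and 2 without Sham 1, 58 and 4 without PHx 1, 82 and 9 without PHx 3, and 160 and 6 without PHx 4. Without Sham 4 edgeR still gave 2241 genes at an unadjusted p under 0.05 and DESeq2 called 558 higher and 50 lower, while DESeq2 on all 6 libraries called 727 and 84.

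Among the genes with at least 5 CPM after PHx, the largest rises were in Vgll3 (log2 fold change 3.10), a transcription cofactor, and Ltbp2 (2.99), a matrix protein of the family that binds latent TGF-beta. Dach1 (2.98), a transcription factor, and Cdh11 (2.89), a cadherin of mesenchymal cells, followed. Upk1b rose by 2.88, Olfml2b by 2.84, Col1a2 by 2.78, Timp1 by 2.65, Slit3 by 2.60 and Msln by 2.53 on the log2 scale. Vgll3, Dach1, Upk1b, Olfml2b, Cdh11 and Timp1 were scarce in sham, at 0.660, 0.951, 0.911, 1.495, 1.51 and 1.54 CPM. The 3 genes that fell were Dmbt1, a secreted scavenger receptor, from 22.6 ± 10.3 to 1.74 ± 0.50 CPM, Galnt15, with a log2 fold change of -1.31 ± 0.11, and Cyp2d22, a cytochrome P450, from 177 ± 9.01 to 90.1 ± 17.7 CPM. Dmbt1 lies on chromosome 7 (131032060 to 131121628) and Cyp2d22 on chromosome 15 (82370527 to 82380260). Cyp2d22 belongs to a family of similar genes, so its counts may hold reads of relatives.

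**Figure D1:**
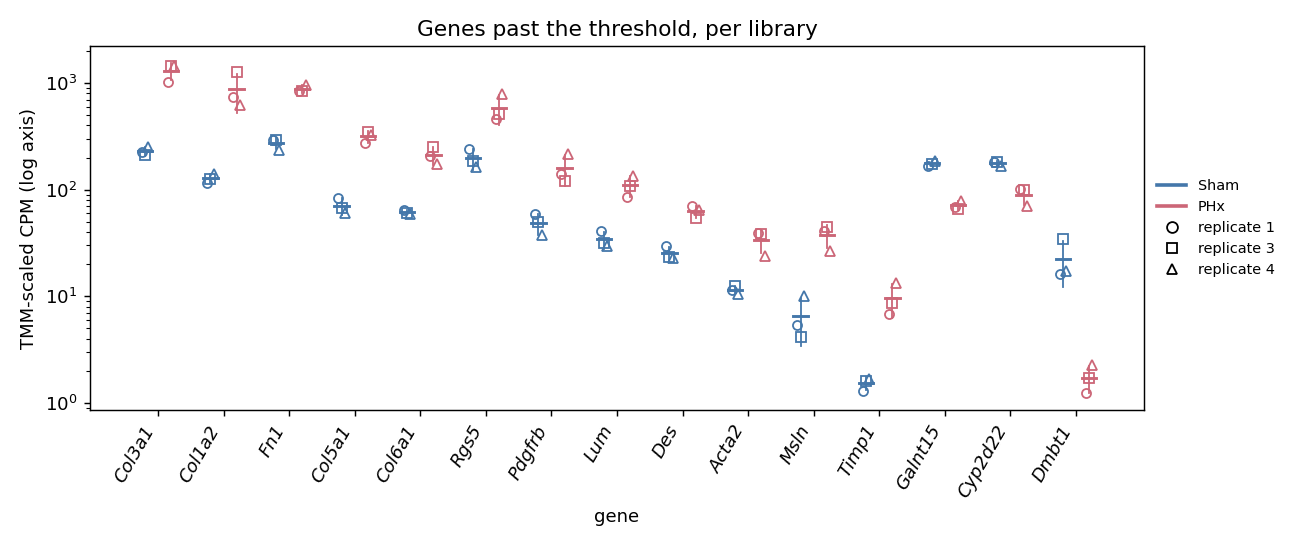
TMM-scaled CPM on a log axis for 15 called genes in each library, with sham in blue and PHx in red, symbols for the replicate numbers, horizontal lines for the means and vertical lines for ± SD (n = 3). The PHx libraries lie above the sham libraries for the first 12 genes, as for Col3a1 at 1306 against 229 CPM, and below them for Galnt15, Cyp2d22 and Dmbt1.

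Of 27 tested genes for collagens, basement membrane and matrix enzymes, 12 rose, none fell and 15 did not pass, and 20 were higher when adjusted over the list alone. The list median was 1.04. Col3a1, Col5a1 (2.16 ± 0.17), Col6a1 (1.78 ± 0.15) and Fn1 (1.69 ± 0.14) had the smallest adjusted p-values, and the median of the 12 called members was 1.95. The list shifted upwards against all other genes by camera (adjusted p = 8.62e-20), but not with an estimated correlation (adjusted p = 0.1002). Stellate and fibroblast markers moved with it. Of those 18 genes 9 rose, none fell and 9 did not pass, and 17 were higher when adjusted over the list alone, with a median of 1.31. Des, an intermediate filament protein of stellate and muscle cells, rose by 1.30 ± 0.15, and Lum, a small matrix proteoglycan, by 1.68 ± 0.20. That list's camera adjusted p was 9.35e-22, and with an estimated correlation the adjusted p was 0.0636.

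Some contractile genes rose in the same libraries. Of 15 genes listed for endothelial-mesenchymal transition 4 rose, Fn1, Acta2 (1.55 ± 0.20), Tagln (1.98 ± 0.27) and Myl9 (1.45 ± 0.22), 11 did not pass, and 10 were higher when adjusted over the list alone. Acta2, Tagln and Myl9 encode an actin and other proteins of the contractile apparatus of smooth muscle and myofibroblasts. The list's camera adjusted p was 4.04e-08, and 0.0636 was the adjusted p with an estimated correlation. Of 13 smooth muscle and pericyte markers 4 rose, including Rgs5 (1.58 ± 0.25) and Pdgfrb (1.71 ± 0.26), 9 did not pass, and 6 were higher when adjusted over the list alone. Its camera adjusted p was 4.55e-07, with an adjusted p of 0.170 with an estimated correlation. Of 9 mesothelial markers Upk1b and Msln rose and 7 did not pass, with 6 higher when adjusted over the list alone and a median of 1.68. The mesothelial camera adjusted p was 4.52e-07, and the adjusted p was 0.397 with an estimated correlation. Col1a2 and Col3a1 belong to the collagen and the stellate list, and Acta2 to the transition, smooth muscle and stellate lists, so these results are not independent.

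**Figure D2:**
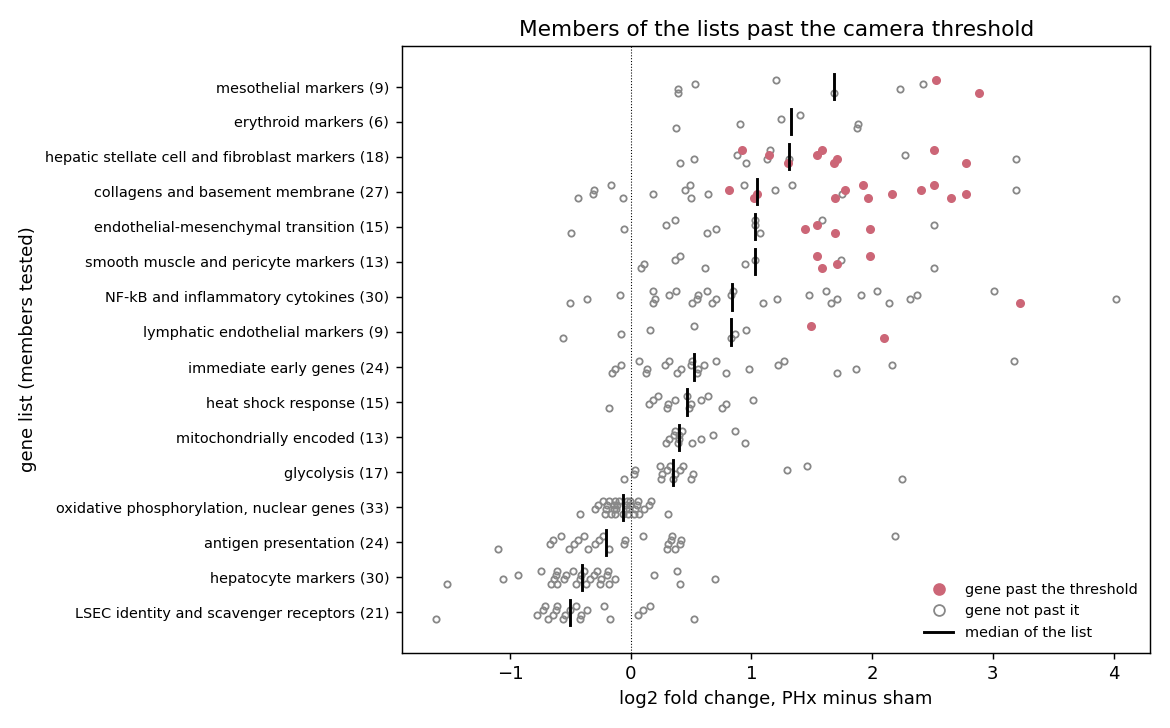
Log2 fold change (PHx minus sham) of every tested member of the 16 lists past the camera threshold, with called genes filled, genes not called open and a black line at each list's median. Filled points lie in the matrix, mesenchymal, mesothelial, lymphatic and NF-kB lists, and the medians run from -0.51 for sinusoidal identity to 1.68 for the mesothelial markers.

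None of the 21 genes for sinusoidal endothelial identity and scavenger receptors passed over all genes, and 12 were lower when adjusted over the list alone. The list shifted downwards by camera (adjusted p = 8.94e-08), with a median log2 fold change of -0.51 and 17 negative members, but not with an estimated correlation (adjusted p = 0.413). The mean level of its members was 9.91 ± 0.02 log2 CPM in sham and 9.43 ± 0.30 in PHx. Stab1 and Stab2, the scavenger receptors that take up hyaluronan and other waste molecules, had log2 fold changes of -0.78 ± 0.24 and -0.61 ± 0.21 (adjusted p = 0.260 and 0.301). Clec4g (-0.55) and the transcription factor Gata4 (-0.36) also had PHx libraries that lay below all sham libraries, without passing the test. DESeq2 called Stab1, Clec4g, Kdr and Bmp6, with adjusted p of 0.0224, 0.0409, 0.0382 and 0.0380. Lyve1, a hyaluronan receptor, had a log2 fold change of 0.16 ± 0.29.

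Other endothelial genes fixed in advance did not pass either. Log2 fold changes were -0.71 for Kdr, a receptor for VEGF, -0.34 for Cdh5, the cadherin of endothelial junctions, -0.21 for Pecam1, 0.65 for Cd34, -0.15 for the flow-responsive factor Klf2 and -0.28 for the nitric oxide synthase Nos3. Among secreted factors they were -0.17 for Wnt2, 0.37 for Wnt9b, 0.53 for Rspo3, 0.56 for Hgf, -0.42 for Bmp2, -0.92 for Bmp6, -0.66 for Angpt2, -0.29 for Tgfb1, -0.46 for Inhbb and 0.07 for Igfbp7. The proliferation marker Mki67 stood at 0.47 ± 0.18 and the cell cycle inhibitor Cdkn1a at 0.53 ± 0.49. Of 40 cell cycle genes none passed over all genes or when adjusted over the list alone, and their median was 0.12 (camera adjusted p = 0.919). On simulated counts the model recovered 26% of the genes changed by a log2 size of 1.

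**Figure D3:**
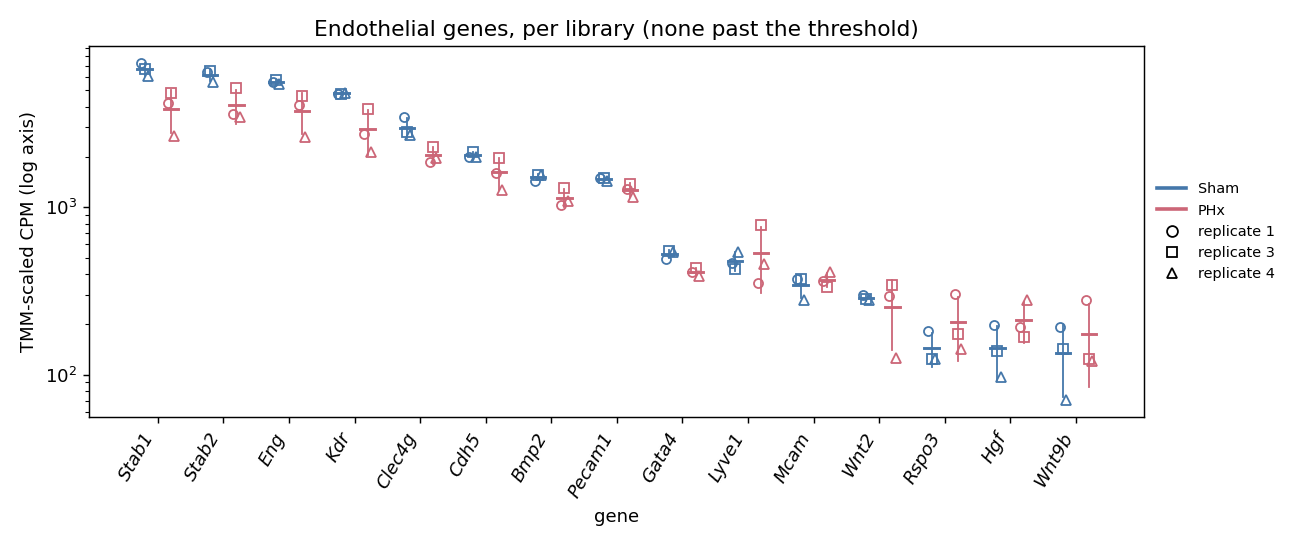
TMM-scaled CPM on a log axis for 15 endothelial and angiocrine genes in each library, with sham in blue, PHx in red, symbols for the replicate numbers, horizontal lines for means and vertical lines for ± SD (n = 3). Stab1 had a mean of 6676 CPM in sham and 3889 CPM in PHx and Mcam 342 and 369 CPM, and none of the 15 genes was called by edgeR.

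Single members of other endothelial lists rose. Tgfb3, a ligand of the TGF-beta family, rose by 1.52 ± 0.18 and was the called member of 29 angiocrine factors (5 higher when adjusted over the list alone). Heyl, a Notch target, rose by 1.94 ± 0.20 among 17 Notch pathway genes (4 higher and 2 lower when adjusted over the list alone). Ptgis, the prostacyclin synthase, rose by 1.66 ± 0.28 among 15 shear stress genes, and Arhgef17 by 1.23 ± 0.16 among 17 YAP and TAZ targets. These 4 lists did not shift by camera, with adjusted p of 0.0814, 0.598, 0.463 and 0.454. Of 9 lymphatic endothelial markers 2 rose, Pdpn (2.10 ± 0.27) and Thy1 (1.49 ± 0.20), both also known from fibroblasts, and 7 did not pass. When adjusted over the list alone 5 were higher and 1 was lower. The lymphatic list's camera adjusted p was 0.00148, with an adjusted p of 0.170 with an estimated correlation.

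Inflammatory and stress lists shifted upwards by camera with few or no called members. Of 30 NF-kB and cytokine genes only the chemokine Ccl7 was called, rising by 3.23 ± 0.42 from 0.527 to 4.95 CPM, and the list median was 0.84 (adjusted p = 0.000139, and 0.616 as the adjusted p with an estimated correlation). Immediate early genes had a median of 0.53 and heat shock genes a median of 0.46, with no called member among 24 and 15. Their camera adjusted p-values were 0.00387 and 0.000237, and the adjusted p was 0.719 and 0.533 with an estimated correlation. Of the heat shock genes 2 were higher when adjusted over the list alone. The most abundant of them, Hsp90ab1, had a log2 fold change of 0.19 ± 0.16. Neutrophil markers differed between libraries, with mean levels of 3.54, 2.99 and 0.88 log2 CPM in Sham 1, 3 and 4 and 4.95, 0.82 and 7.11 in PHx 1, 3 and 4. Immediate early genes averaged 9.01 log2 CPM in PHx 4 and between 6.55 and 8.21 in the other libraries. Their call was lost without Sham 3, at an adjusted p of 0.511, and in 2 of the 6 fits that left out a library.

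Metabolic lists shifted without a called gene. The 13 mitochondrially encoded genes had a median of 0.40 (camera adjusted p = 0.00179, and adjusted p = 0.616 with an estimated correlation), with 0.32 ± 0.23 for COX1, and the call was lost without PHx 1 (adjusted p = 0.255). The 17 glycolysis genes had a median of 0.35 (camera adjusted p = 0.00355, and adjusted p = 0.653 with an estimated correlation), and the call was lost without PHx 4 (adjusted p = 0.162). The 33 nuclear genes of oxidative phosphorylation had a median of -0.06 (camera adjusted p = 0.0457, and adjusted p = 0.616 with an estimated correlation), and the 24 antigen presentation genes a median of -0.20 (0.0412, and adjusted p = 0.684 with an estimated correlation). Each of these last lists kept its call in 3 of the 6 fits that left out a library. H2-D1, a class I histocompatibility gene whose close relatives can share its reads, had a log2 fold change of -0.51 ± 0.21.

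Markers of other blood and liver cells were measured in the same libraries. The 30 hepatocyte markers had a median of -0.40 and no called member (camera adjusted p = 4.36e-05, and adjusted p = 0.616 with an estimated correlation). Alb, the albumin gene, stood at 972 ± 206 CPM in sham and 710 ± 232 CPM in PHx. The hepatocyte call was lost without PHx 3, at an adjusted p of 0.269. The 6 tested erythroid genes had a median of 1.33 (camera adjusted p = 0.00148, and adjusted p = 0.413 with an estimated correlation), with 2 higher when adjusted over the list alone and 1.89 ± 0.46 for Hba-a1, which has a near-identical copy and was called by DESeq2 (adjusted p = 0.000389). The 14 neutrophil markers had a median of 3.12 and did not pass (adjusted p = 0.0533), with Ngp at 4.19 ± 1.91 and S100a9 at 2.93 ± 1.80. Kupffer cell and macrophage markers had a median of -0.47 (adjusted p = 0.136), and Clec4f, a Kupffer cell receptor, stood at -1.75 ± 0.91. T and NK cell, B and plasma cell, monocyte and dendritic cell, platelet and cholangiocyte markers had medians of -0.25, 0.19, 0.83, 0.63 and 0.27 and did not pass. The leukocyte gene Ptprc had a log2 fold change of 1.10 ± 0.88.

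Across the 40 lists 12 shifted upwards and 4 downwards by camera, and none with an estimated correlation. With fry, which asks whether a list's genes move one way, 8 lists passed, all upwards. These were the collagen, transition, stellate, smooth muscle, lymphatic, angiocrine, periportal and continuous capillary lists. Periportal and arterial, pericentral and continuous capillary endothelial genes had medians of 0.27, 0.29 and 0.32 with camera adjusted p of 0.0533, 0.160 and 0.274. Of the periportal and arterial genes 7 were higher and 1 was lower when adjusted over the list alone, while its most abundant members included Ltbp4 at -0.65 ± 0.28. Thbd, an abundant member of the pericentral list, stood at 0.47 ± 0.24. Genes of VEGF and angiopoietin signalling had a median of -0.32 and a mean of opposite sign, and those of the BMP and TGF-beta pathway, with Eng at -0.57 ± 0.23, a median of -0.02. The interferon, unfolded protein, hypoxia, cholesterol, Wnt, leukocyte adhesion and cell cycle inhibitor lists did not pass, with medians of -0.07, 0.10, 0.31, 0.01, 0.03, 0.16 and 0.39. For the cholesterol, Wnt and leukocyte adhesion lists the camera direction was opposite to the sign of the median.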

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

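The fit without Sham 4 by DESeq2, the fits with a neutrophil covariate and the fit without both Sham 4 and PHx 4 were chosen after the data were seen. All 161 higher genes kept a positive log2 fold change and an unadjusted p under 0.05 in each alternative where they were measured, which was 143 genes under the filter of at least 5 CPM in 3 libraries and all 161 elsewhere. Counts of higher and lower genes stayed within 1.5 times of 161 and 3 with median-of-ratios factors, upper-quartile factors, limma-voom, the 5 CPM filter, the log2 threshold of 1 and the neutrophil covariate. They were 359 and 30 with no filter on low counts, 727 and 84 with DESeq2, 16 and 1 at an adjusted p under 0.01, 14 and 0 with the hepatocyte covariate, 558 and 50 with DESeq2 without Sham 4, and 24 and 1 without Sham 4 and PHx 4. The stricter threshold shows its own cause, and for the others the cause was not tested. Fewer samples entered the fits that left out libraries. Leaving out each library in turn gave 0 to 160 higher and 0 to 9 lower genes. Those fits had the same number of libraries, so sample number alone does not explain the range. With the replicate number as a block the counts were 14 and 1. Same-numbered libraries did not deviate together (correlations of -0.09, -0.23 and 0.03), no library correlated best with its own number, and the block ended the call of antigen presentation (adjusted p = 0.0695). It added the neutrophil, monocyte and dendritic, periportal and arterial, and Kupffer lists (adjusted p = 0.000237, 0.0170, 0.0239 and 0.0258), so 19 lists passed. With an estimated correlation 0 lists passed, fry passed 8 of the 40, of which 5 were among the 16, and leaving out each library passed 13 to 20, of which 12 to 15 were among the 16. Single genes that had not passed changed sign. Lyve1 was at -0.39 with the hepatocyte covariate. With the neutrophil covariate Mcam was at -0.0010, Ptprc at -0.30, S100a9 at -0.54 and Wnt2 at 0.023. S100a9 is among the markers averaged in that covariate, so its sign change there tests nothing. Without Sham 4 and PHx 4 Mcam was at -0.10, Ptprc at -0.11 and Wnt2 at 0.13, and Mcam was at -0.032 with DESeq2 without Sham 4. Leaving out each library gave -0.039 to 0.084 for Igfbp7, -0.25 to 0.38 for Lyve1, -0.052 to 0.17 for Mcam, -0.46 to 0.15 for Wnt2 and -0.15 to 0.68 for Wnt9b. Alternatives that apply to RPKM values alone were not run.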

Other observations

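The tests of an equal rise in other cell types, of the neutrophil markers, of the male-biased hepatocyte genes and of single lists across splits, and the genes in the first paragraph below, were chosen after their values were seen.

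Enzymes that modify and cross-link collagen were among the 161 higher genes, with log2 fold changes of 2.41 for Lox, 2.15 for Loxl1, 1.03 for Loxl2 and 2.03 for Plod2. Families of gene symbols were tested for enrichment among the higher genes by Fisher's exact test, 1-sided, over 454 families and 14286 protein-coding genes. The collagens (7 of 38, adjusted p = 8.29e-05) and the Adamtsl genes (3 of 5, adjusted p = 0.00308, Adamtsl1, Adamtsl4 and Adamtsl5) passed. Fisher's test treats genes as independent, and the collagens overlap the matrix list above. Genes of resting stellate cells were also higher, including the retinol esterifying enzyme Lrat (0.92), the transcription factors Hand2 (1.14), Tcf21 (1.29) and Lhx2 (0.91), and the carotenoid cleaving enzyme Bco1 (1.36). The soluble guanylate cyclase genes Gucy1a2, Gucy1a3 and Gucy1b3, whose product binds nitric oxide, rose by 2.09, 1.29 and 1.22. C3, the central complement component, rose from 446 to 1103 CPM.

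Matrix and mesenchymal genes were higher after PHx. Several explanations for this were examined, and the values argue against the first. The median of 23 stellate cell genes outside the matrix was 0.95 with a bootstrap interval of 0.88 to 1.29. Its lower end of 0.881 speaks against activation of resident stellate cells without more of them. That interval covers the spread between genes only, while the list's mean level was 6.05 ± 0.25 log2 CPM in sham and 6.99 ± 0.13 in PHx. Pdgfrb, Rgs5 and Des are in the list, so it is not made of resting-cell genes alone. The intervals of hepatocyte, Kupffer and T and NK cell markers reached at most 0.126, below the stellate marker interval from 1.04. Those lists were picked after their values were seen, so this cannot decide whether a lower endothelial share raised all other types alike. The cell-type lists not used there had positive medians, from 0.19 for B and plasma cells to 3.12 for neutrophils, so a rise in several types is not addressed. The stellate markers also include matrix genes such as Col3a1. More stellate cells or fibroblasts in the purified cells cannot be told apart from other causes. The level set in advance was 0.973, at 0.5 times the median of the called matrix genes. The stellate median of 0.954 lay just under it, while the interval included it. The called genes were picked for their change, and the median of all 27 matrix genes was 1.04. Per library, the matrix level minus the level of the stellate genes was 1.07 ± 0.22 log2 in sham and 1.31 ± 0.24 in PHx (exact permutation p = 0.4, smallest possible 0.1). No level was set in advance for that difference. Endothelial cells losing identity may contribute, since 20 pan-endothelial genes had a median of -0.409 (interval -0.48 to -0.27), but a larger share of stellate RNA would lower them too.

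Neutrophil markers were high in PHx 1 and PHx 4, and a group effect of PHx on them is left open by PHx 3, whose mean of 0.824 log2 CPM lay 0.06 below the lowest sham library, where the sham SD was 1.40. All 14 of the 14 markers were higher in PHx 4 than in each sham library, which describes that library and tests no cause, so neutrophils carried along with the purified cells are left open too. S100a9 reached 1440 CPM in PHx 4 against 10.8 to 140 in sham. Sele and Selp, adhesion molecules of activated endothelium, stood at 546 and 1066 CPM in PHx 4 against at most 61.9 and 159 in sham, and were not called. In PHx 1 and PHx 3 Sele stood at 72.5 and 137 CPM, above every sham library. Selp stood at 154 and 153 CPM there, below the highest sham library. No biological explanation for the levels of Sele and Selp in PHx 4 was tested.

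Hepatocyte genes known to be expressed more in males had a median of -0.90 over 11 genes, of which 9 were negative and none was called. Over all libraries a lower amount of hepatocyte RNA is left open, with a difference from the hepatocyte marker median of -0.496 (interval -1.05 to -0.28). Against the sham mean, the difference was 0.273 in PHx 3 (interval -0.57 to 0.67), which leaves it open. In PHx 4 it was -4.34 (interval over genes -5.29 to -0.92), which argues against less hepatocyte RNA as the only cause in that 1 library. There 9 of the 11 genes lay below every sham library, with Cyp4a12b, Hsd3b5 and Elovl3 at 0 CPM. C6 and Cyp7b1 lay above every sham library instead, at 85.4 and 18.2 CPM. In PHx 3 also 9 of the 11 genes lay below every sham library, so that count is not particular to PHx 4. The mean of the 11 male-biased genes was -0.62 log2 CPM in PHx 4, 1.67 in PHx 3 and 2.74 in PHx 1, against 2.61 to 2.84 in sham. Mup20, which has near-identical relatives, stood at 2.00 CPM in PHx 4 against 34.5 to 68.4. The sex of the animals is not stated in the sources used here, and transcripts of the sex chromosomes were not examined for it. A difference between animals was not tested.

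The 6 libraries can be divided into 2 groups of 3 in 10 ways, too few for a share under 0.05. The real division called 161 genes higher and 3 lower, and the highest of the other divisions 0 and 0, so 1 of 10 gave as many in each direction. For gene lists the real division passed 16 and the highest other also 16, so 2 of 10 gave as many. The camera p was smaller in the real division than in any other for the collagen, stellate, transition, smooth muscle, mesothelial, lymphatic and sinusoidal identity lists. The same held for the angiocrine, periportal and continuous capillary lists, which did not pass camera. For a single list chance alone gives this 1 time in 10. For hepatocyte, NF-kB, immediate early and glycolysis genes 6 of the 10 divisions gave a p at least as small, and so did 5 for antigen presentation.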
